A study of Rattus norvegicus with 32 samples.

How the data were processed

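RNA from rat ROSE A25 cells was measured on 2-colour arrays of 342 named cDNA sequences, with 4 arrays for each of 7 siRNA knockdowns, 2 arrays of ROSE A25 against ROSE 199 and 2 of scrambled siRNA against untransfected ROSE A25. RNA was taken 48 h after the last transfection. Each array came as 2 scanner files, one per dye, with 1296 spots in 16 blocks. Per the file headers the scanner files hold spot intensity on a linear scale, with background given apart and not subtracted, and a flag code per spot that was treated as a score of spot quality (other). The deposited value table of the authors holds a log2 ratio per array, turned so that both dye orientations of a knockdown and of ROSE A25 point the same way, while the direction of its scrambled columns is not settled, and how it was made is not given in the sources used here. Its 2 columns per duplex are not independent, so it was used only as an alternative. The scanner and its software are not given in the sources used here.

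Of the 64 scanner files 4 were identical to another, and 31 distinct images lay behind them. In 2 arrays labelled siJunb and in both scrambled arrays the files of the 2 dyes came from different images. The siJunb files were paired by image, and pairing them as deposited was an alternative. The scrambled arrays could only be used across images. The arrays had 2 spot layouts, with 168 spots labelled differently, and AHR was left out for this reason. The other names were used as each layout gives them. Names were matched to gene symbols through the supplied table of gene symbols (68 by symbol, 54 by synonym) or by textbook name (83), and 137 names had none.

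Intensities were computed from mean spot values. They were background corrected by normexp with an offset of 50, and log2 ratios were normalised within arrays by loess with a span of 0.3 and 4 iterations. Blank, unnamed and marked spots had no weight in the loess fit. Marked spots were then left out, which kept 708 to 954 named spots per channel file, and the spots of a name were averaged. Ratios were turned to knockdown over scrambled, and the arrays of a duplex were averaged where both orientations were measured. The 14 duplex means were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 1 mean per factor, 7 residual degrees of freedom and a moderated variance (prior degrees of freedom 2.99). A gene was called at an adjusted p (Benjamini-Hochberg, per knockdown) below 0.05, in a 2-sided test. Of 341 genes, 211 were measured in all 14 duplexes. A spot counted as above background when its mean signal exceeded the background mean by 2 background SD, and 278 genes were above background in at least 1 channel on at least 50% of the arrays. The ROSE and scrambled comparisons have 1 dye-swapped pair each and were read by size alone, at least 2-fold the same way in both orientations.

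Gene lists were fixed in advance, 18 in all, and those with at least 3 measured members were tested by camera in its pre-ranked form on the moderated statistics with a preset correlation of 0.01, again with an estimated correlation, and by fry. Fry asks whether the genes of a set move, on balance, one way, and does not compare them with other genes. Effects among the 7 factors were adjusted over the list alone and over all genes. Each knockdown was also set against the mean of the other 6, since all ratios share scrambled RNA. What a shared scrambled RNA alone would give was simulated in 100 draws.

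These choices, most alternatives and the rule for naming genes were set before the data were examined. The pairing of the siJunb files by image, the omission of AHR, the fit without the arrays labelled siHmga2 and siJunb, the image series as a random block and the scrambled channels set against ROSE A25 of the same dye were decided after the data were seen. Named by rule were the targeted gene, the other factors, and up to 8 higher and 8 lower genes per knockdown, the largest among those past 0.05 with the same sign in all 4 arrays, or the 3 with the smallest p where fewer than 3 passed. For ROSE A25 the rule took up to 12 genes each way, for scrambled up to 5, and for gene lists 2 to 4 members. Genes named from the fit without the arrays labelled siHmga2 and siJunb lie outside the rule. Alternatives covered background correction, normalisation, spot statistic, filters, marked spots, replicate unit, dye orientation, variance estimate, adjustment, source of values and each duplex left out. The pipeline was tested on simulated data in 5 draws. It called 322 of 343 genes with a planted log2 change of 2, 130 of 347 with a change of 1 and 30 of 11040 unchanged ones, with no wrong sign, and 6.22% of all calls were false. The simulated duplexes had independent noise, no shared scrambled RNA and the same mean brightness of a gene on every array. These rates therefore need not hold for the real arrays, which differ in signal and share a control.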

Results

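The study asked how 7 transcription factors act on one another and on other genes in rat ovarian surface epithelium cells transformed by an oncogenic KRAS. ROSE 199 is the parental rat ovarian epithelial line, and ROSE A25 is its KRAS-transformed derivative. ROSE A25 cells were transfected with siRNA against Fosl1, Gfi1, Hmga2, Junb, Klf6, Otx1 or Rela, or with scrambled siRNA, and RNA was taken 48 h after the last transfection. Each factor was targeted by 2 independent siRNA duplexes, and each knockdown RNA was hybridised against scrambled RNA on a 2-colour cDNA array in both dye orientations. This gave 4 arrays per factor and 28 knockdown arrays. A further 2 arrays compared ROSE A25 with ROSE 199, and 2 arrays compared scrambled siRNA with untransfected ROSE A25. The array carried 342 named sequences, most of them spotted 3 times. Between 14.97% and 97.6% of the named spots were above background in a channel of the knockdown arrays, and the median signal ranged from 169 to 2231. The replicate was the siRNA duplex (n = 2 per factor), and its value was the mean of its dye-swapped arrays. Turned the same way, the dye orientations of a duplex correlated across genes at r from -0.86 (siJunb N2) to 0.08 (siOtx1 N2). In all other duplexes r was negative. Genes on the knockdown arrays thus tended to follow the dye, and a duplex mean averages profiles that were often opposite. Nothing in the labels says whether the duplexes were transfected into separate cultures, so p-values measure the spread between these samples. The small number of arrays limits the precision.

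The targeted mRNA was lower in every array of 2 of the knockdowns. In the Otx1 knockdown, Otx1 was at a log2 ratio of -1.48 to scrambled (SE 0.31, n = 2 duplexes, lower in 4 of 4 arrays), which leaves 35.8% of its level. In the Fosl1 knockdown, Fra1 (Fosl1), a FOS-family partner of JUN proteins, was at -0.86 (SE 0.25, lower in 4 of 4 arrays), which leaves 55.2%. In limma's moderated test over all genes the adjusted p was 0.0587 for Otx1 and 0.164 for Fra1, so neither passed 0.05. Copeb (Klf6) in the Klf6 knockdown was at -0.21 (SE 0.33, lower in 2 of 4 arrays), and a second sequence named Klf6 was at 0.56 in the single duplex that measured it. The NF-kappaB sequence, whose subunit the name does not give, was at -0.04 (SE 0.22, lower in 3 of 4 arrays) in the Rela knockdown. HMGI-C (Hmga2), an architectural chromatin protein, was at -0.09 (SE 0.26, lower in 3 of 4 arrays) in the arrays labelled siHmga2. JunB was at 0.75 (SE 0.64, lower in 1 of 4 arrays) in the arrays labelled siJunb, from 1.60 in replicate 1 and -0.09 in replicate 2, and whether the dye orientations of the replicate 1 arrays are labelled correctly is not settled. JunB was at -2.82 in replicate 2 of the arrays labelled siHmga2, with -3.59 and -2.06 in its 2 arrays. Upa (Plau) was at -3.23 and ER81 ETV1 (Etv1) at -3.14 in the same duplex, so JunB did not stand out there. Whether the dye orientations of that duplex are labelled correctly is not settled either. The scanner files name no Gfi1 spot. In the authors' value table for the same arrays every targeted gene was lower in 4 of 4 columns, from -0.89 for NF-kappaB to -2.03 for HMGI-C. In the arrays labelled siHmga2, siJunb, siKlf6 and siRela the mean of the target was thus not lower by more than its SE, and what is given for these knockdowns rests on their labels, as it does for siGfi1.

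**Figure D1:**
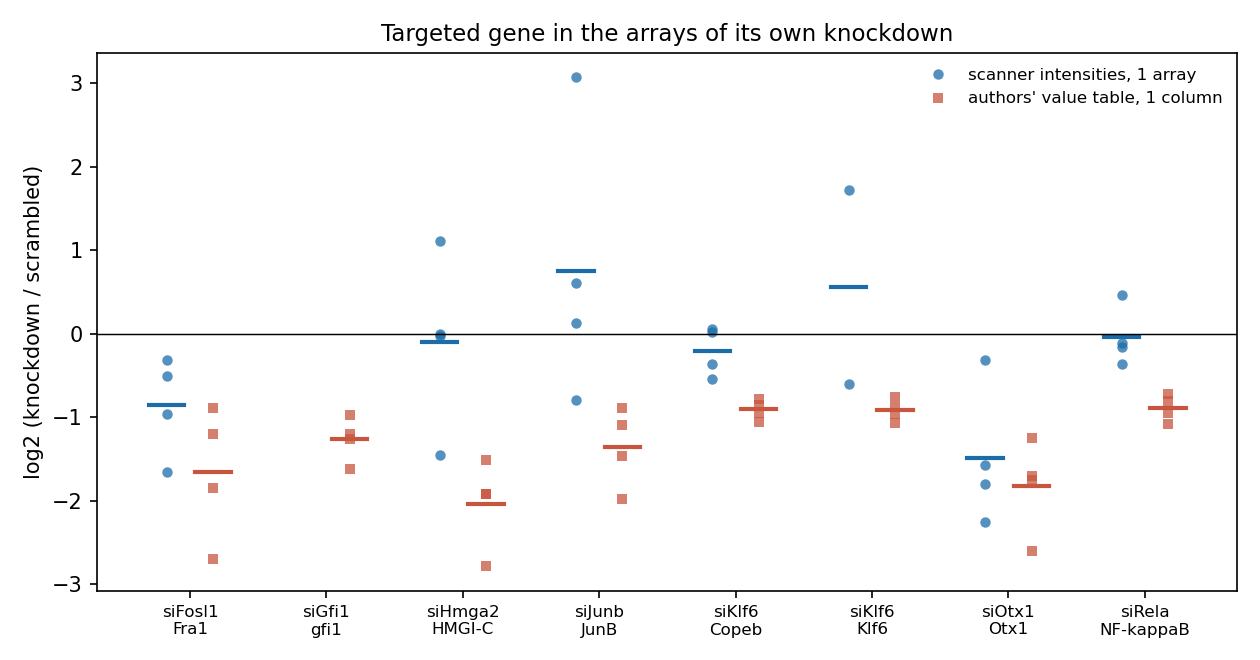
Log2 ratio of knockdown to scrambled (y axis) of the targeted gene in each knockdown (x axis, with the name on the array). Circles are single arrays computed from scanner intensities, squares are single columns of the authors' value table, and horizontal lines are means over duplexes. All table values lie below 0, whereas only Fra1 and Otx1 lie below 0 in all 4 arrays of the scanner data.

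Knockdown of Otx1, a homeobox transcription factor, had the largest number of called genes in this fit. A total of 15 of 340 genes passed, 9 higher and 6 lower. Against the mean of the other 6 knockdowns none of 310 genes passed in siOtx1. The changes below are thus against scrambled RNA and are not shown to be particular to Otx1. Schlafen2 (Slfn2) rose by a log2 ratio of 1.66 (SE 0.37). Mkp3 (Dusp6) and Mkp4 (Dusp9), phosphatases that inactivate MAP kinases, rose by 1.45 (SE 0.23) and 1.28 (SE 0.24). HEC (Ndc80), a kinetochore component, and RHAMM (Hmmr), a hyaluronan receptor that also binds the mitotic spindle, rose by 1.18 (SE 0.24) and 1.09 (SE 0.25). LAP2 (Tmpo), a protein of the inner nuclear membrane, rose by 1.14 (SE 0.18), and Thrombospondin 1 (Thbs1), a matrix glycoprotein, by 1.10 (SE 0.20). ORP150 (Hyou1), a chaperone of the endoplasmic reticulum, fell by 2.18 (SE 0.38) and MMP-3 (Mmp3), a matrix metalloproteinase, fell by 1.33 (SE 0.32). PKC-zeta-interacting protein fell by 1.17 (SE 0.26). The drug-efflux transporter MDR1 (Abcb1b) and the transporter MoatB each fell by 1.13 (SE 0.26 and 0.27). All of these had the same sign in 4 of 4 arrays, and limma's adjusted p lay between 0.0135 and 0.0431. Thrombospondin 1 and 1 other called gene, Rsu-1 (Rsu1), were not above background on most arrays. The count moved with the processing. It was 45 (22 higher, 23 lower) without the arrays labelled siHmga2 and siJunb, 1 without siOtx1 replicate 2, and 0 with plain background subtraction or with the series of scanned images as a random block. It was 3 with adjustment over all knockdowns together, 4 with the knockdown in Cy3 alone and 5 with median centring in place of loess. Image series nearly coincides with factor, so batch and knockdown cannot be told apart by that block.

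Without the arrays labelled siHmga2 and siJunb, a choice made after the data were seen, Otx1 itself passed in its knockdown (limma adjusted p 0.0187). In that fit CyclinD1 (Ccnd1), which drives entry into the cell cycle, rose by 1.12 (SE 0.26), and Mki67, a marker of proliferating cells, by 1.03 (SE 0.24). The collagenase MMP-1 (Mmp1) fell by 1.20 (SE 0.27), Egfr, the EGF receptor, by 0.97 (SE 0.23), and Ets-2 (Ets2), an ETS transcription factor, by 1.19 (SE 0.32). All of these had the same sign in 4 of 4 arrays. Limma's adjusted p was 0.0243 for CyclinD1, 0.0202 for Mki67, 0.0187 for MMP-1, 0.0258 for Egfr and 0.0394 for Ets-2. Genes given from this fit, here and for the other knockdowns, were chosen after their values were seen.

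Knockdown of Fosl1 raised Mkp3 by 1.61 (SE 0.23) and a sequence named on the array as a transcript associated with monocytes by 1.37 (SE 0.19). Both were higher in 4 of 4 arrays, with limma adjusted p of 0.0105 and 0.00903, and no other gene of 337 passed. The next genes by p were RHAMM at 1.21 (SE 0.25), HEC at 1.18 (SE 0.24) and the kinesin Kif22 at 1.32 (SE 0.31), with limma adjusted p of 0.0552, 0.0552 and 0.134. Without the arrays labelled siHmga2 and siJunb, 20 genes passed, 11 higher and 9 lower. They then included RHAMM, HEC, Kif22, Mki67 at 0.99 (SE 0.24) and P9k42a (S100a4), a calcium-binding protein linked to metastasis, at 1.17 (SE 0.23). The lower genes included Fra1 (limma adjusted p 0.0407), Wdnm-2 at -1.25 (SE 0.18), Grn, the growth factor progranulin, at -1.18 (SE 0.21) and RhoA at -0.78 (SE 0.17). No gene passed without siFosl1 replicate 1, and in the authors' value table HEC and the monocyte-associated transcript had the opposite sign in this knockdown, at -1.53 and -1.52.

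In the arrays labelled siKlf6 the same 2 sequences were higher, Mkp3 by 1.82 (SE 0.23) and the monocyte-associated transcript by 1.59 (SE 0.19), with limma adjusted p of 0.00414 and 0.00241. Both were higher in 4 of 4 arrays, and none of the other 337 genes passed. ID2 (Id2), an inhibitor of helix-loop-helix transcription factors, was at -1.19 (SE 0.30), Cyr61 (Ccn1), a secreted matricellular protein, at -0.83 (SE 0.21), and the lipoxygenase Alox15 at 0.97 (SE 0.21), with limma adjusted p of 0.173, 0.173 and 0.139. Without the arrays labelled siHmga2 and siJunb, 8 genes passed in limma, with ID2, Cyr61, Grn and CSF-1 (Csf1) among the 4 lower ones. Without siKlf6 replicate 2 the count was 0, and without replicate 1 it was 1.

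Knockdown of Gfi1 raised 1 gene of 340, the monocyte-associated transcript, by 1.31 (SE 0.19, higher in 4 of 4 arrays, limma adjusted p 0.0132). HMGI-C was at 1.15 (SE 0.26) and Gli1, a transcription factor of the hedgehog pathway, at -1.06 (SE 0.24, lower in 3 of 4 arrays), both with limma adjusted p of 0.159. Mkp3 was at 0.77 (SE 0.23). Leaving out either duplex of siGfi1 ended the call. Without the arrays labelled siHmga2 and siJunb the count was 5, and the 4 higher genes included Histone H3.3, HMGI-C and P55CDC (Cdc20), an activator of the anaphase-promoting complex measured in 1 duplex.

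No gene passed limma's test in the Rela knockdown (323 genes tested, 9 at an unadjusted p below 0.05). The genes with the smallest p were the monocyte-associated transcript at 0.56 (SE 0.19), Nras at 0.48 (SE 0.17) and MMP-3 at -0.82 (SE 0.32), each with a limma adjusted p of 0.997. No gene passed in the arrays labelled siHmga2 (44 of 334 at an unadjusted p below 0.05) or siJunb (20 of 333). In the arrays labelled siHmga2 the smallest p belonged to ROK-alpha (Rock2), a Rho-associated kinase, at -1.18 (SE 0.23, limma adjusted p 0.148). Fibrilin-1 (Fbn1), a microfibril protein, was at -1.87 and Beta3integrin (Itgb3) at -2.63, each measured in 1 duplex. In the arrays labelled siJunb, Histone H3.3 was at 2.17 (SE 0.46, 3.50 in replicate 1 and 0.85 in replicate 2), Cathepsin D (Ctsd) at 0.81 (SE 0.21) and Map kinase kinase 1 (Map2k1) at -0.84 (SE 0.22), with limma adjusted p of 0.255, 0.383 and 0.383. The profiles of the 2 duplexes correlated across genes at r = -0.35 for siHmga2 and -0.36 for siJunb. With 1 duplex left out, 80 genes passed in siHmga2 without its replicate 1 and 24 in siJunb without its replicate 2.

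Over the 7 knockdowns, 20 calls fell on 15 genes, and 2 genes were called in more than 1 knockdown. These were Mkp3 (siFosl1, siKlf6, siOtx1) and the monocyte-associated transcript (siFosl1, siGfi1, siKlf6, siOtx1), and both were also the only genes past 0.05 in limma's F test of any change (adjusted p 0.00742 and 0.00136, 310 genes tested). Each list of higher genes is short, and independent lists of the same lengths would share 0.0119 genes between siFosl1 and siKlf6. All ratios were taken against scrambled RNA. If that RNA were 1 extract that varied as much as a duplex, a median of 19 unchanged genes would be called in 2 or more knockdowns in 100 simulated draws. Part or all of the shared calls may therefore come from the shared control. When each knockdown was set against the mean of the other 6, which removes a shared control, limma called 1 gene, the monocyte-associated transcript, at -1.33 (SE 0.21, adjusted p 0.0239) in the arrays labelled siJunb.

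**Figure D2:**
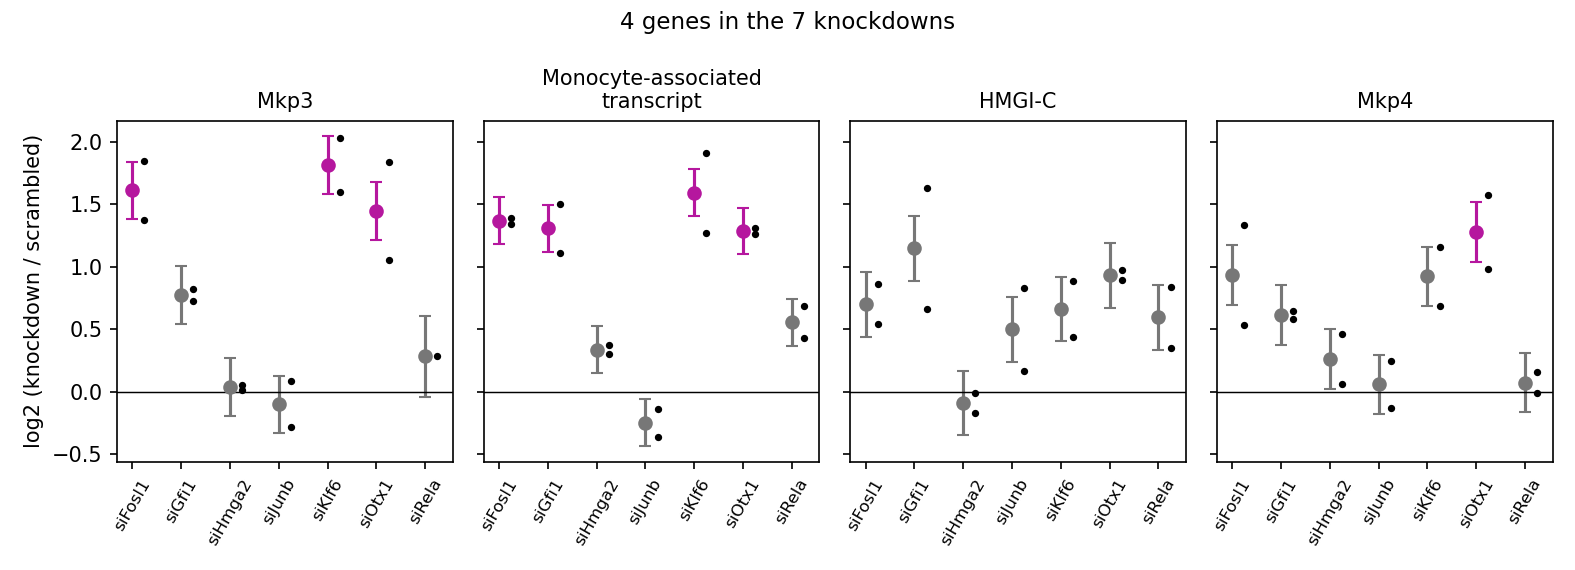
Log2 ratio of knockdown to scrambled (y axis) of Mkp3, the monocyte-associated transcript, HMGI-C and Mkp4 in the 7 knockdowns (x axis). Large points are means with SE, small points are the duplexes, and coloured means passed limma's adjusted p of 0.05. Mkp3 in siRela was measured in 1 duplex, and HMGI-C passed in none of the knockdowns, where its values ranged from -0.09 to 1.15.

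The profiles of the 2 duplexes against one factor correlated across genes at a median r of 0.41 (-0.36 to 0.62, 7 factors), and profiles of different factors at 0.24 over 84 pairs. Genes are not independent replicates, so these values only describe the profiles. Among the 5 factors other than Hmga2 and Junb the medians were 0.44 and 0.35, with a covariance of 0.064 between factors. Unchanged profiles that shared 1 scrambled RNA, given the spread of a duplex, had a simulated r of 0.50 and a covariance of 0.23. An r near 0.50 follows from that spread, which was assumed and not measured, and the simulated covariance lay above the observed 0.064. The simulation therefore cannot tell how much of the r between factors comes from a shared control. After the mean over the 7 knockdowns was removed, the medians were 0.01 within factors and -0.08 between them.

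Few effects of a knockdown on the other factors passed a test, and Gfi1 was not measured in the scanner data. Of 36 effects measured in the scanner data, none passed limma's test over all genes, 7 had an unadjusted p below 0.05, and 1 passed adjusted over the list alone. That 1 was HMGI-C, at 1.15 (SE 0.26, higher in 4 of 4 arrays, limma adjusted p 0.0457 over the list) in the Gfi1 knockdown. The count was 0 over the list with plain background subtraction, a normexp offset of 0, median centring, loess per print block, the duplex number as a block, marked spots kept or dim probes left out, and it changed in 13 of 14 fits that left out 1 duplex. HMGI-C was also above 0 in 4 of 4 arrays of siOtx1 (0.93), siFosl1 (0.70), siKlf6 (0.66) and siRela (0.60), each with SE 0.26 and limma adjusted p of 0.0873 or more over the list. Values of 1 sign in all 5 of these knockdowns may in part or in full come from the shared scrambled RNA. The largest values of other factors were Otx1 at 1.40 in the arrays labelled siJunb and 1.02 in siGfi1 (SE 0.44 each, each measured in 1 duplex) and JunB at -1.07 (SE 0.64) in the arrays labelled siHmga2, none of them past 0.05 in limma. By the values the authors deposited, 13 of 42 effects passed over the list alone and 12 over all genes. HMGI-C was there at 1.24 in the Gfi1, 0.85 in the Otx1 and 0.75 in the Klf6 knockdown. In the same table JunB was at -1.21 in the Fosl1 and -0.81 in the Klf6 knockdown, and Fra1 was at 1.13 in the Rela, 0.92 in the Klf6 and -1.14 in the Hmga2 knockdown.

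KRAS-transformed ROSE A25 cells were compared with the parental ROSE 199 cells. Of 326 genes measured in both dye orientations, 6 were at least 2-fold higher and 7 at least 2-fold lower in both. P9k42a (S100a4) was 9.18-fold higher, an S-100 related sequence 6.59-fold, the monocyte-associated transcript 3.44-fold, HMGI-C 3.32-fold, the anti-proliferative factor Btg1 2.66-fold and CyclinD1 2.26-fold. Collagen alpha was 20.7-fold lower, and Lot1 (Plagl1), a zinc finger protein that restrains growth, 9.01-fold. FISP-12 (Ccn2), a matricellular growth factor, was 3.58-fold lower, Fibronectin (Fn1) 3.38-fold, Steroid sensitive gene 2.76-fold, Thrombospondin 1 2.69-fold and ORP150 2.57-fold. These folds are means of 1 dye-swapped pair of arrays, with no replicate check and no test. With 1 orientation alone 30 to 35 genes were at least 2-fold higher and 31 to 59 lower. Unrelated orientations would also share some of these. Their number was not computed, so the 6 higher and 7 lower genes are not shown to exceed it. The remaining genes mostly followed the dye, since the orientations correlated across genes at r = -0.26 once turned the same way, and K-ras (Kras) itself was at -1.33 in one orientation and 2.66 in the other. In the authors' value table, which correlated with the scanner means at r = 0.65 across genes, K-ras was at 4.11 and 4.48.

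**Figure D3:**
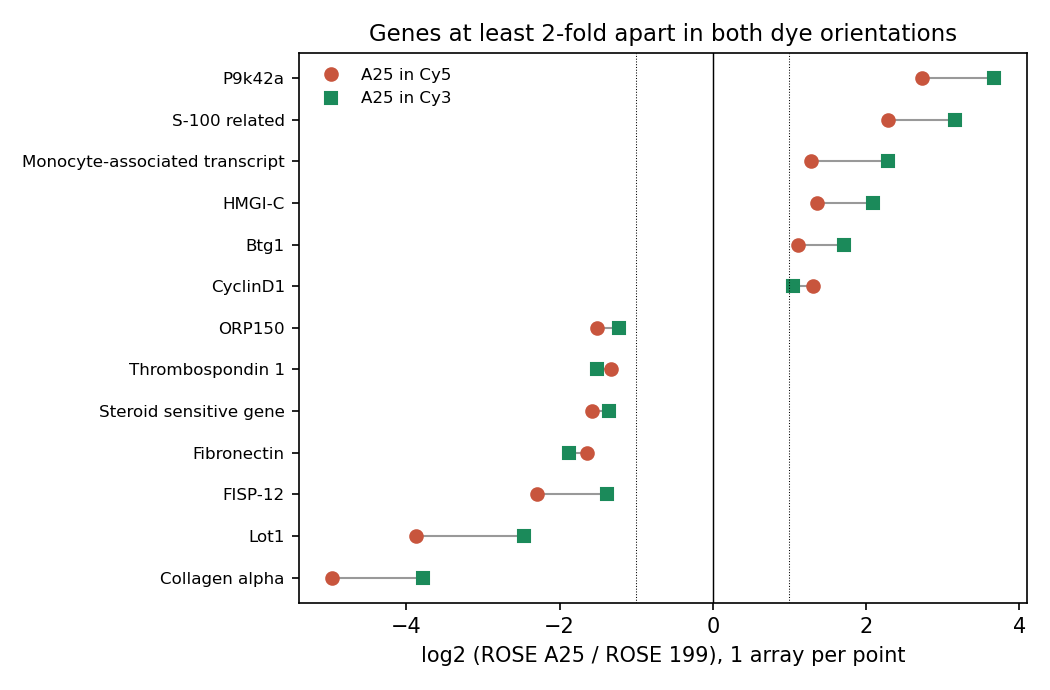
Log2 ratio of ROSE A25 to ROSE 199 (x axis) of the 13 genes at least 2-fold apart in both dye orientations (y axis). Circles are the array with ROSE A25 in Cy5, squares the array with ROSE A25 in Cy3, and dotted lines mark 2-fold. Collagen alpha lies lowest, at -4.96 and -3.78, and P9k42a highest, at 2.72 and 3.67.

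Scrambled siRNA was compared with untransfected ROSE A25 cells to estimate off-target effects. Of 301 genes, 10 were at least 2-fold higher and 9 at least 2-fold lower in both orientations. With 1 orientation alone 51 to 57 were higher and 19 to 49 lower, so unrelated orientations would also share some genes. How many was not computed, so the 10 higher and 9 lower genes are not shown to exceed that number. GADD153 (Ddit3), a transcription factor of the endoplasmic reticulum stress response, was 6.85-fold higher, P5 protein 5.13-fold, the BCL2-interacting protein Bnip3 4.91-fold, JunD (Jund) 4.82-fold and GAPDH (Gapdh) 4.16-fold. Antiquitin (Aldh7a1), an aldehyde dehydrogenase, was 11.3-fold lower, FHL2 (Fhl2) 9.82-fold, Copeb (Klf6) 8.15-fold, Polyhomeotic (mPh2) 7.65-fold and Cca1 4.68-fold. The orientations correlated at r = -0.02 across genes, and the channels came from different hybridisations, because the scrambled channels of both arrays were from 1 image and the ROSE A25 channels were those of the ROSE arrays. In the authors' value table, where the 2 columns of this comparison correlated at r = 0.11 and their direction is not settled, the same genes lay mostly near 0, with GADD153 at 0.64 and -0.64. Both dyes of the 1 scrambled image are labelled scrambled, although each array is described as scrambled against ROSE A25. Whether both of these channels hold scrambled RNA is thus not settled. A difference between slides or a mislabelled channel therefore cannot be told apart from an effect of the transfection here.

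None of the 12 gene lists with at least 3 measured members shifted in any knockdown by limma's camera test with its preset correlation (84 tests, 8 at an unadjusted p below 0.05). The smallest adjusted p was 0.0922, for the targeted transcription factors in the Gfi1 knockdown (5 measured, 4 above 0, median 0.56), and 0.0272 with an estimated correlation. This list passed in siGfi1 with the duplex number as a block (camera adjusted p 0.045) or with median spot values (0.019), and in siJunb with loess per print block (0.00404). EGF family ligands and growth factors passed in siKlf6 without dim probes (0.031), though not with an estimated correlation (0.24), with which the other 3 of these calls held. Of the 10 measured genes of MAPK feedback and immediate early response, Mkp3 was the only member called, in 3 knockdowns, and the list's smallest adjusted p was 0.485 (siKlf6). Mkp1 (Dusp1) and Egr-1 (Egr1) of this list were at -0.48 (SE 0.19) and 0.62 (SE 0.28) in the Otx1 knockdown. Of 11 proteases, inhibitors and invasion genes, MMP-3 fell in the Otx1 knockdown and no other member was called (smallest adjusted p 0.507, siRela). Of 5 matrix genes, Thrombospondin 1, which was not above background on most arrays, was called higher in the Otx1 knockdown and no other member was called (0.78, siOtx1). No member of the other lists was called in any knockdown. Their smallest adjusted p values in camera were 0.231 for EGF family ligands and growth factors (4 genes, siKlf6) and for mesenchymal markers (4 genes, siHmga2), and 0.409 for the AP-1 and ATF family (5 genes, siFosl1) and for NF-kappaB targets and cytokines (3 genes, siKlf6). They were 0.485 for housekeeping controls (3 genes, siRela), 0.507 for cell cycle and proliferation (5 genes, siOtx1), 0.511 for actin cytoskeleton and TGF-beta or SRF associated genes (6 genes, siHmga2) and 0.712 for apoptosis and survival (3 genes, siGfi1). With an estimated correlation 8 of the 84 tests passed in camera, 6 of them for the 3 apoptosis genes, whose estimated correlation was -0.73. No list passed in limma's fry test. Of the epithelial markers 2 were measured, of the stress genes 1, and of the interferon, leukocyte, endothelial and granulosa lists none, so these were not tested.

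The genes that differed between ROSE A25 and ROSE 199 were followed in the knockdowns. The 6 genes higher in ROSE A25 shifted further up in 5 knockdowns, with median log2 ratios of 0.72 in siFosl1, 0.54 in siGfi1, 0.60 in siKlf6, 0.88 in siOtx1 and 0.30 in siRela. Camera's adjusted p was 5.55e-07 in siGfi1 and 8.69e-05 in the other 4, and the adjusted p was 0.0368 in all 5 with an estimated correlation. The members above 0 numbered 5 of 6 in siFosl1 and siKlf6 and 6 of 6 in siGfi1, siOtx1 and siRela, and the monocyte-associated transcript was the only member called singly. P9k42a and the S-100 related sequence moved alike, at -0.79 and -0.85 in siJunb N1 and 0.98 and 1.07 in siHmga2 N2. Whether they are a single signal was not tested, and the preset correlation treats them as nearly independent. With the knockdown in Cy5 alone the list was no longer past 0.05 in siFosl1, siGfi1, siKlf6 and siRela, with medians of 0.38, 0.21, 0.54 and 0.0084, and in the authors' value table its median in siFosl1 was 0.033. The medians were 0.34 in the arrays labelled siHmga2 and -0.28 in those labelled siJunb, with camera adjusted p of 0.0791 and 0.11. The 7 genes lower in ROSE A25 had medians from -0.44 (siJunb) to 0.11 (siGfi1), and none of the 7 tests passed (smallest camera adjusted p 0.0791, siGfi1). Of these 7 genes, Thrombospondin 1 rose and ORP150 fell in the Otx1 knockdown. The lists came from other arrays of the series and share no channel with the knockdown arrays. Against the mean of the other 6 knockdowns the higher list was lower in the arrays labelled siJunb (median -0.79, 0 of 6 above 0, camera adjusted p 6.09e-05, 0.0429 in fry). It was higher in siGfi1 and siOtx1 (medians 0.25 and 0.41, camera adjusted p 0.00951 and 0.016), but not past 0.05 in fry (adjusted p 0.18 and 0.226). With an estimated correlation none of these passed (adjusted p 0.101 in siJunb, 0.169 in siGfi1 and siOtx1). In siFosl1 and siKlf6 it was no longer past 0.05, with medians of 0.41 and 0.28, and its median was -0.09 in siRela.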

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

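Tests chosen only after the result was seen were the tests of a shared scrambled channel, siRela left out of one of them included, and of dye bias. The comparison of each knockdown with the other 6 and the search for extreme arrays were planned.

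Among 78 groups of 4 values, 5 held an array far from the others, and chance alone gives this in about 5% of such groups, so these need no cause beyond chance. HEC in siOtx1 was highest, at 1.94, in replicate 2 with the knockdown in Cy5. The monocyte-associated transcript in siRela was highest, at 0.95, in replicate 1 with the knockdown in Cy3. NF-kappaB was lowest, at -0.47, in siKlf6 replicate 1 with the knockdown in Cy3, and highest, at -0.0013, in siOtx1 replicate 1 with the knockdown in Cy5. The median signal of the knockdown channel in siRela was highest, at 399.8, in replicate 1 with Cy3.

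The monocyte-associated transcript differed between knockdowns. In the arrays labelled siJunb it lay below the mean of the other 6 knockdowns, at a log2 difference of -1.33 (SE 0.21, limma adjusted p 0.0239). It was the only gene of 310 past 0.05 in this contrast over the 7 knockdowns. No gene passed with median centring, median spot values, no background correction, plain background subtraction or the image series as a random block, and leaving out 1 duplex gave 0 to 72 calls. The difference was between its rise in 4 knockdowns and a value of -0.25 in the arrays labelled siJunb.

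Mkp3 and the monocyte-associated transcript were called higher in several knockdowns, which is the shape a shared scrambled channel would give. A gene-specific dye effect is argued against, since all 28 arrays of the called knockdowns, counted for both genes and in both dye orientations, had the higher value. A scrambled RNA shared by all knockdowns predicts equal shifts, but among the 5 knockdowns other than siHmga2 and siJunb both genes differed in limma's F test (p 0.0178 for Mkp3, 0.0274 for the transcript). Without siRela, the dimmest, Mkp3 still differed in that test (p 0.0461) and the transcript did not (p 0.688). For Mkp3 this set siGfi1 (0.77) against siFosl1 (1.61), siKlf6 (1.82) and siOtx1 (1.45). Of these, siGfi1 had the lowest median share of spots above background (63.3%, siFosl1 64.6%). Against 1 scrambled extract on all arrays as the whole cause, this is only a weak argument for Mkp3. That cause stays open for the transcript, whose value in siRela was 0.56. These p-values are not adjusted, and a shared control may still give part of either rise.

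The array layout of the knockdown arrays leaves 3 positions unnamed that the layout of the ROSE arrays names AHR, the aryl hydrocarbon receptor. They gave signal, with a log2 ratio of signal to background of 2.05 against 0.13 for blank spots. In the ROSE arrays the same positions gave 2.12. The positions that the knockdown layout itself names AHR gave 0.30 in the knockdown arrays. They were all used in no comparison, because which sequence lies there in the knockdown arrays is not settled. Whether the other spots labelled differently carry the right names in the knockdown arrays was not tested.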

How the results depend on the processing

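Tests chosen only after the data were seen were the fit without the arrays labelled siHmga2 and siJunb, the image series as a random block, the siJunb channels paired as deposited, and the scrambled channels set against ROSE A25 of the same dye. The single genes named by rule were compared 1247 times over 35 alternatives. In 1006 of these they kept their side of the threshold (6 of them, not past it, with another sign), in 163 they were no longer past it, in 75 they newly passed, and in 3 the sign was reversed, all with the authors' value table. Counts and values that answer a comparison were compared 1131 times over 48 alternatives and stayed the same in 921 (40 of them not past the threshold and with another sign). In 172 a count or value moved beyond its bound, in 8 a list or target was no longer past the threshold, in 26 it newly passed, and in 4 it was reversed. Mkp3 and the monocyte-associated transcript were above 0 in siFosl1, siKlf6 and siOtx1 in all alternatives run, except the transcript in siFosl1 with the value table. The counts of called genes held far less well.

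With the authors' value table, the count of called genes was 91 in siFosl1, 57 in siGfi1, 85 in siHmga2, 42 in siJunb, 65 in siKlf6, 89 in siOtx1 and 34 in siRela, and 13 effects among the factors passed over the list alone. 490 calls were made against the mean of the other knockdowns and 202 genes were called in any knockdown by the F test. The size rule gave 46 higher and 42 lower genes for ROSE A25, and the size rule gave 2 higher and 5 lower genes for scrambled. The siRNA target was at -1.66 in siFosl1, -2.03 in siHmga2, -1.35 in siJunb (reversed), -1.82 in siOtx1 and -0.89 in siRela, and the median of the genes higher in ROSE A25 was 0.033 in siFosl1 (no longer past 0.05) and -0.73 in siHmga2 (reversed). The median of the genes lower in ROSE A25 was 0.76 in siJunb (reversed) and the median r of the 2 duplexes of a factor was 0.84. The sign was reversed for Fibrilin-1 in siHmga2 (1.34), HEC in siFosl1 (-1.53) and the monocyte-associated transcript in siFosl1 (-1.52). The direction of its scrambled columns is not settled (r of 0.11 between them), so higher and lower may be exchanged in its 2 and 5 scrambled genes. How that table was made is not given in the sources used here. Its 2 columns summed to 0 in 121 of 328 rows of each siFosl1 duplex, so the spread behind its counts may be too small. The cause of these differences was not tested.

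With the knockdown in Cy5 alone, the count of called genes was 33 in siFosl1, 10 in siGfi1, 17 in siHmga2, 74 in siJunb, 19 in siKlf6 and 31 in siRela, and 0 effects among the factors passed over the list alone. 30 calls were made against the mean of the other knockdowns and 92 genes were called in any knockdown by the F test. The target of the siRNA was at -1.30 in siFosl1, and the median of the genes higher in ROSE A25 was 0.38 in siFosl1 (no longer past 0.05), 0.21 in siGfi1 (no longer past 0.05), 0.54 in siKlf6 (no longer past 0.05) and 0.0084 in siRela (no longer past 0.05). The median r of duplexes of different factors was 0.57. With the knockdown in Cy3 alone, the count of called genes was 7 in siFosl1, 7 in siHmga2, 18 in siJunb, 1 in siKlf6 and 4 in siOtx1, and 2 effects among the factors passed over the list alone. 27 genes were called in any knockdown by the F test and the median of the genes higher in ROSE A25 was 0.52 in siHmga2 (now past 0.05). The median r of duplexes of different factors was 0.63. With each array as an independent sample, the count of called genes was 8 in siFosl1, 2 in siHmga2, 3 in siJunb and 27 in siOtx1, and 0 effects among the factors passed over the list alone. 12 calls were made against the mean of the other knockdowns and 24 genes were called in any knockdown by the F test. The target of the siRNA was at -1.48 in siOtx1. With each array as a sample, the duplex as random block and a dye term, the count of called genes was 15 in siFosl1, 2 in siHmga2, 3 in siJunb and 30 in siOtx1, and 0 effects among the factors passed over the list alone. 10 calls were made against the mean of the other knockdowns and 30 genes were called in any knockdown by the F test. The siRNA target was at -0.86 in siFosl1 and -1.48 in siOtx1. The first 2 settings keep any dye effect of a gene in the ratio, and the last 2 count the arrays of 1 duplex as more samples.

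Without the arrays labelled siHmga2 and siJunb, the count of called genes was 20 in siFosl1, 5 in siGfi1, 8 in siKlf6, 45 in siOtx1 and 2 in siRela, and 2 effects among the factors passed over the list alone. 38 genes were called in any knockdown by the F test, and the siRNA target was at -0.86 in siFosl1 and -1.48 in siOtx1. With the series of scanned images as a random block, the count of called genes was 0 in siOtx1 and 0 effects among the factors passed over the list alone. 0 calls were made against the mean of the other knockdowns. With the siJunb channels paired as deposited, the count of called genes was 4 in siFosl1, 1 in siHmga2 and 5 in siKlf6, and 3 calls were made against the mean of the other knockdowns. Image series nearly coincides with factor and duplex, so the block and the knockdowns can hardly be separated in this fit. The cause of the other changes was not tested, although fewer knockdowns enter the spread when the arrays labelled siHmga2 and siJunb are left out.

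With the duplex number as a replicate block, a pairing of N1 and N2 across factors, 0 effects among the factors passed over the list alone and 1 gene list shift was called. The target of the siRNA was at -1.48 in siOtx1. The differences between N1 and N2 correlated across genes at a median r of -0.05 over 21 pairs of factors (-0.38 to 0.73, 3 pairs above 0.1), so the numbers did not pair the duplexes in general. The profiles labelled siHmga2 and siJunb did follow the number, with r of 0.46 between their N1 and 0.48 between their N2 duplexes. The siOtx1 count was 11 in this fit. The list that passed was the targeted transcription factors in siGfi1 (camera adjusted p 0.045).

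Leaving out 1 duplex at a time, in a fit that assumes a lone duplex varies like the others, gave counts of 0 to 4 in siFosl1, 0 to 2 in siGfi1, 0 to 80 in siHmga2, 0 to 24 in siJunb, 0 to 5 in siKlf6 and 1 to 21 in siOtx1. The F test gave 1 to 27 genes, the contrast against the other knockdowns 0 to 72 calls, the effects among the factors 0 to 3 and the gene lists 0 to 2. Otx1 in its knockdown ranged from -2.02 to -0.94, and Histone H3.3 in siJunb from 0.85 to 3.50. The duplex left out decided the count in siHmga2 (80 without replicate 1), siJunb (24 without replicate 2), siOtx1 (1 without replicate 2) and siFosl1 (0 without replicate 1), and in siGfi1 (0 without either). With 1 dye orientation alone, the size rule gave 30 to 35 higher and 31 to 59 lower genes for ROSE A25 and 51 to 57 higher and 19 to 49 lower for scrambled, because 1 array then has to pass in place of both.

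With plain background subtraction, the count of called genes was 0 in siFosl1, 0 in siGfi1, 0 in siKlf6 and 0 in siOtx1, and 0 effects among the factors passed over the list alone. 0 calls were made against the mean of the other knockdowns and the median of the genes higher in ROSE A25 was 0.74 in siHmga2 (now past 0.05). Without background correction, the count of called genes was 23 in siOtx1 and 2 effects among the factors passed over the list alone. 0 calls were made against the mean of the other knockdowns and the size rule gave 3 higher genes for ROSE A25. The size rule gave 5 higher genes for scrambled and the median of the genes lower in ROSE A25 was 0.12 in siGfi1 (now past 0.05). With a normexp offset of 0, the count of called genes was 6 in siOtx1 and 0 effects among the factors passed over the list alone. The size rule gave 20 lower genes for scrambled and the median of the genes higher in ROSE A25 was 0.57 in siHmga2 (now past 0.05). With median centring in place of loess, the count of called genes was 2 in siHmga2 and 5 in siOtx1, and 0 effects among the factors passed over the list alone. 0 calls were made against the mean of the other knockdowns and the size rule gave 35 lower genes for scrambled. The median of the genes higher in ROSE A25 was 0.65 in siHmga2 (now past 0.05) and the median of the genes lower in ROSE A25 was -0.70 in siJunb (now past 0.05). With loess per print block, the count of called genes was 0 in siGfi1 and 4 in siKlf6, and 0 effects among the factors passed over the list alone. 1 gene list shift was called. With log ratios scaled between arrays, the count of called genes was 7 in siKlf6 and 23 in siOtx1, and 8 calls were made against the mean of the other knockdowns. The target of the siRNA was at -1.45 in siOtx1. With median in place of mean spot values, the count of called genes was 0 in siGfi1 and 1 gene list shift was called. 0 calls were made against the mean of the other knockdowns. Without dim probes, 0 effects among the factors passed over the list alone and 1 gene list shift was called. The median of the genes lower in ROSE A25 was -0.50 in siJunb (now past 0.05). With spots kept that the scanner software had marked, 0 effects among the factors passed over the list alone and 5 calls were made against the mean of the other knockdowns. The target of the siRNA was at -1.65 in siOtx1 and the median of the genes lower in ROSE A25 was 0.28 in siGfi1 (now past 0.05). The cause was not tested for these settings, except that leaving out dim probes tests fewer genes. The list called was the targeted transcription factors in siJunb with loess per print block and in siGfi1 with median spot values, and EGF family ligands and growth factors in siKlf6 without dim probes, which did not pass with an estimated correlation (adjusted p 0.24).

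With each knockdown fitted alone, the count of called genes was 0 in siFosl1, 0 in siGfi1, 13 in siKlf6 and 55 in siOtx1, and the target of the siRNA was at -1.48 in siOtx1. With adjustment over all knockdowns together, the count of called genes was 3 in siOtx1. With an estimated correlation in camera, 8 gene list shifts were called. With fry in place of camera, the median of the genes higher in ROSE A25 was 0.30 in siRela (no longer past 0.05). Against the mean of the other 6 knockdowns, the median of the genes higher in ROSE A25 was 0.41 in siFosl1 (no longer past 0.05), -0.79 in siJunb (now past 0.05), 0.28 in siKlf6 (no longer past 0.05) and -0.089 in siRela (reversed), and the median of the genes lower in ROSE A25 was 0.20 in siGfi1 (now past 0.05). With the mean over the knockdowns removed, the median r of duplexes of different factors was -0.075. With an estimated correlation the calls newly made against the other 6 knockdowns were not past 0.05 (adjusted p 0.101 for both). Fitting a knockdown alone leaves 1 residual degree of freedom, the contrast and the removed mean take out what all ratios share, and the other causes were not tested.

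With a 1.5-fold rule, the size rule gave 16 higher and 11 lower genes for ROSE A25, and the size rule gave 19 higher and 20 lower genes for scrambled. With centring on housekeeping genes, the size rule gave 3 higher and 14 lower genes for ROSE A25, and the size rule gave 4 higher and 14 lower genes for scrambled. With limma's test borrowing the spread between duplexes, the calls were 18 higher and 18 lower genes for scrambled. With each scrambled channel set against the ROSE A25 channel of the same dye, the size rule gave 16 lower genes for scrambled. The 1.5-fold rule calls more genes by construction, and the cause of the other differences was not tested.

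Signal over background differed between the knockdowns, and whether it set the number of calls was not tested. The share of named spots above background had a median of 48.5% in the channels of siRela, 49.4% in siJunb and 54.9% in siHmga2. It was 63.3% in siGfi1, 64.6% in siFosl1, 73.2% in siKlf6 and 84.9% in siOtx1, the knockdown with the most calls. With simulated changes of log2 size 1 the fit found 37.5% of the changed genes, and with size 2 it found 93.9%, so smaller changes were mostly out of reach. The simulation had no shared scrambled RNA and the same mean brightness on every array, so these shares need not hold for the real arrays.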

Other observations

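The fit without the arrays labelled siHmga2 and siJunb, and all tests of hypotheses given here except the re-pairing of duplexes and the removal of 1 gene from a list, were chosen only after the result was seen.

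In the fit without the arrays labelled siHmga2 and siJunb, RHAMM, HEC and Mki67 were called in both the Fosl1 and the Otx1 knockdown, Kif22 in the Fosl1 knockdown, and CyclinD1 and E2f5 (0.96), a transcription factor of the cell cycle, in the Otx1 knockdown. These genes were picked after their values were seen, and the fixed list of cell cycle and proliferation genes did not shift in the fit of all 7 knockdowns (smallest camera adjusted p 0.507), where P27Kip (Cdkn1b) was at 0.058 and RB (Rb1) at -0.038 in the Otx1 knockdown. Histone H3.3 was called higher in 4 knockdowns, from 0.92 in siFosl1 to 1.16 in siOtx1. Grn was called lower in 3, at -1.18 in siFosl1, -1.06 in siKlf6 and -0.75 in siOtx1. In total 59 genes were called in at least 1 of the 5 knockdowns and 15 in at least 2. All 5 ratios share scrambled RNA, so part or all of this overlap can come from the control. In the authors' value table the called genes had the same sign for 16 of 19 in siFosl1, 4 of 5 in siGfi1, 8 of 8 in siKlf6 and 44 of 45 in siOtx1, and both tables stem from the same hybridisations.

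Pairing the 14 duplexes at random into 7 pairs gave at least the real 20 calls in 16 of 100 pairings, the real one included. Chance thus cannot be excluded for the grouping by factor. Re-pairing keeps shifts that all duplexes share, so it does not test whether the calls themselves arise by chance. The highest of the other pairings gave 67 calls, several times the real count, which points to a structure of the samples. What that structure is was not tested.

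HMGI-C and JunB were not lower in the arrays labelled with their siRNA, though both were lower in the authors' value table. A swap between the siHmga2 and siJunb arrays predicts a lower HMGI-C in the arrays labelled siJunb. It was at 0.50 there (SE 0.26, lower in 2 of 4 arrays), with 0.16 in replicate 1 and 0.83 in replicate 2. This cannot decide on a swap, because the target was not lower by more than its SE in siKlf6 (-0.21) and siRela (-0.04) either. Replicate 2 of the arrays labelled siHmga2 may hold a JunB knockdown, since JunB was at -2.82 there, but across the other genes its profile correlated at 0.142 with the authors' siJunb profile, below their siGfi1 (0.206) and siRela (0.193) profiles and above that of its own label (-0.243). The profiles of these arrays followed the replicate number rather than the label, with r across genes between siHmga2 and siJunb of 0.46 for replicate 1 and 0.48 for replicate 2, and of -0.35 and -0.36 within the labels. Exchanged dye orientations in the replicate 1 arrays could turn these signs and stay open. Those profiles correlated with the authors' profiles of the same duplex at 0.137 (siHmga2) and -0.155 (siJunb), both nearer 0 than the lowest r in the other factors (0.321). Replicate 2 correlated at -0.320 in siHmga2 and 0.128 in siJunb. Exchanged orientations in siHmga2 replicate 2, which would turn its JunB value, therefore stay open too. A JunB knockdown in replicate 2 of siHmga2 stays open, though low JunB is also what the authors' values give for that label. Dim arrays stay open too, with a median share of spots above background of 54.9% in siHmga2, against 64.6% in siFosl1. The single channels overlapped, from 18.1% to 75.2% in siHmga2 and from 34.9% to 82.3% in siFosl1. Brightness alone thus did not separate these arrays. No biological explanation was tested.

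Genes higher in ROSE A25 than in ROSE 199 were higher still in 5 knockdowns. That a single gene carries this list is argued against by camera with its preset correlation, in which 5 of the 5 knockdowns kept the list past the threshold without the monocyte-associated transcript. With an estimated correlation none of them did, with adjusted p from 0.0982 to 0.121. P9k42a and the S-100 related sequence, which moved alike, both stayed in the list in this test. A scrambled channel shared by all knockdowns stays open, because only 1 of the 5, siRela, differed from the mean of the other 4 (camera adjusted p 0.0215, lower), and not with an estimated correlation (0.149) or in fry (0.182). The scrambled RNA may thus have been lower in these genes than the knockdown RNA for a reason other than the targeted factors, and a response to siRNA against any of the factors was not tested apart from it.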
